A study of Mus musculus with 6 samples.

How the data were processed

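Gene expression was measured by RNA-seq of dorsal root ganglia of mouse embryos, with 3 cKO and 3 Ctrl libraries. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with an mRNA library kit; whether the kit keeps strand is not given in the sources used here. Per the submitters' processing notes, HISAT2 2.2.1, Bowtie2 2.4.5 and RSEM 1.3.1 were used with the genome build GRCm38 (mm10), without their role or order. The authors deposited estimated counts per gene and library, not normalized, with RSEM named in the processing notes; most were whole numbers (88.4% to 88.6% of values per library, counted as whole only where the deposited value had no fractional part). They also deposited TPM values per library, used here only as a second level per gene, and FPKM values per library with the authors' group means. The FPKM columns the authors deposited were used only to compare libraries: they summed to 590156 and 614728 in Ctrl replicate 1 and cKO replicate 1, and to 548068 to 551964 in the other 4. No column was left without a sample. Of 17971 genes, 17838 matched a gene identifier in the RefSeq table of GRCm38.p6, 17694 of them protein coding, and coordinates come from that build. No mitochondrially encoded gene was in the table used here.

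Depth was 16464264 to 17446385 counts per library. Counts were rounded to whole numbers, and genes were kept by the filterByExpr function of edgeR, which left 14338 genes and removed 3633. The comparison used TMM scaling and the robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SEs were derived from the log2 fold change and its F statistic. CPM values, counts scaled to a common library size, use the TMM library sizes. On simulated counts for the same genes, the main model recovered 62% of genes changed 1.3-fold, 94% of those changed 1.5-fold and 100% of those changed 2-fold or 4-fold, and 2.73% of its calls were false. The blocked model recovered 64% and 96% of the 1.3-fold and 1.5-fold changes, with 4.76% false calls. The changed genes were drawn only from genes with many counts, at a single fixed spread, so recovery among genes with few counts was not measured. The main model was run on counts without litter effects and the blocked model on separate counts with them, so their shares do not compare the models. The biological coefficient of variation was 7.79%, and 4.94% with the block. Groups did not overlap for 16.6% of genes, where chance gives 10%.

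Titles number the replicates 1 to 3 in both groups, and same-numbered samples share the start of their sample code. Each number is called a litter here, since the controls are described as littermates. The deviations of same-numbered libraries from their group means correlated at 0.328, 0.205 and 0.184 across genes, and the first principal component (30.4% of variance) set the number 1 libraries apart from the rest. The numbers were therefore taken to pair the samples. The model without the block had been fixed as the main one before the data were examined. Blocked values are given where they change the call of a gene or list described here.

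A set of 51 gene lists (1004 distinct genes) for cell types, neuron classes, pathways and other tissues was fixed before the data were examined, and 50 had members to test. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and with an estimated correlation and fry as alternatives. Named genes followed a rule fixed at the same time: Ybx1 and its relatives; the 12 largest rises and 12 largest falls among called genes with non-overlapping groups, at least 5 CPM and no placeholder name; for each list described, up to 4 called members, or else the 2 most highly expressed; and the sex-linked genes. Exceptions are marked in the text, and some genes that the rule names are not reported here.

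Alternatives fixed before the data were examined were the size factors of DESeq2 1.42.0, library totals, the DESeq2 and limma-voom tests, other filters, a fold threshold of 1.5, the replicate block and leaving out each library. The pseudocount alternative applies only to TPM or FPKM and was not run. Added after seeing the data were models without litter 1, 2 or 3, a blocked model with an offset for transcript length and GC content, and blocked models with other scalings. Length and GC content were those of the longest GENCODE M21 transcript of each gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.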

Results

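Dorsal root ganglia, the clusters of sensory nerve cells and their glia beside the spinal cord, were profiled by RNA-seq in mouse embryos at stage E13.5. The 3 cKO libraries came from embryos in which both floxed copies of Ybx1 were exposed to Cre recombinase under Wnt1 control, which acts in the neural crest lineage that forms these ganglia. The 3 Ctrl libraries came from littermates with floxed Ybx1 and no Cre. The labels describe all embryos as male and the samples as biological replicates. Each library held between 16464264 and 17446385 estimated counts over 17971 genes, of which 14338 had enough counts to be tested.

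The comparison asked which transcripts differ between the ganglia of cKO and Ctrl embryos. All cKO embryos carried Cre and no Ctrl embryo did. For every gene, an effect of Cre or its transgene therefore cannot be told apart from loss of Ybx1. Ybx1 (gene identifier 22608, chromosome 4, 119277327 to 119296265, GRCm38) encodes a cold-shock domain protein that binds mRNA. It fell from 851 ± 66.3 to 122 ± 14.4 normalised CPM (counts scaled to library size; SD, n = 3 libraries per group), a log2 fold change of -2.80 with an SE of 0.10 and an edgeR adjusted p of 8.42e-08. The 3 Ctrl libraries held 927, 809 and 817 CPM and the 3 cKO libraries 137, 122 and 108, so every library went with its genotype label. The counts cover the whole gene, including exons outside the deleted part. The ganglia also hold cells outside the neural crest lineage, such as blood and endothelial cells, which would keep Ybx1. The reads left in cKO therefore do not measure intact mRNA in the targeted cells. The relatives Ybx3 (log2 fold change 0.12, SE 0.09, edgeR adjusted p 0.736) and Ybx2 (-0.09, SE 0.23, adjusted p 0.937) did not pass the test.

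**Figure D1:**
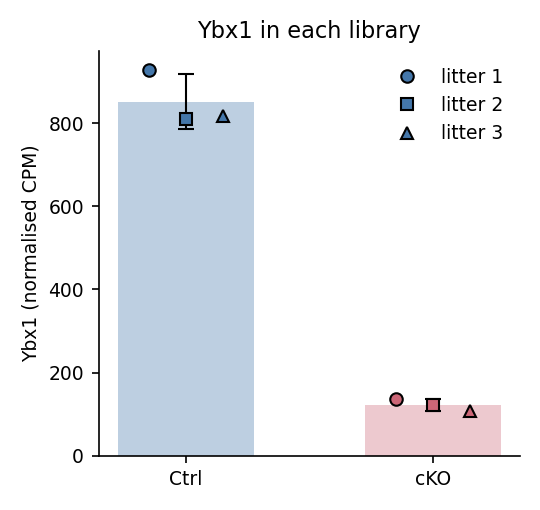
Normalised Ybx1 CPM in each library, by genotype. Bars are group means, error bars SD over 3 libraries, and marker shapes give the replicate number; the 3 cKO libraries lie between 108 and 137 and the 3 Ctrl libraries between 809 and 927.

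Beyond Ybx1, a small set of genes was called in the main model, and a larger one when the replicate number was used. In the main model 69 genes changed at an edgeR adjusted p under 0.05, of which 16 were higher and 53 lower in cKO. The median log2 fold change was 0.88 among the genes called higher, and -0.51 among the genes called lower with Ybx1 left out. The genes called higher include Wnt1 and 3 neighbours of Ybx1, described below. When the replicate number was added as a block, 764 genes passed, 253 higher and 511 lower, and these included all 69. In that model the median was 0.29 among the genes called higher and -0.29 among those called lower, Ybx1 included. Scaled by library totals alone, 44 genes passed and 63.6% of them were lower, against 76.8% in the main analysis; with the block and library totals, 396 were higher and 403 lower, so the excess of falls depends on the scaling. The count moved with the libraries used: it was 58 without Ctrl replicate 1, 20 without cKO replicate 2, 31 without cKO replicate 3, 20 without Ctrl replicate 2, 18 without Ctrl replicate 3 and 104 without cKO replicate 1. Without both libraries numbered 1, which stood apart from the rest, 731 genes passed, and 1252 with the block.

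**Figure D2:**
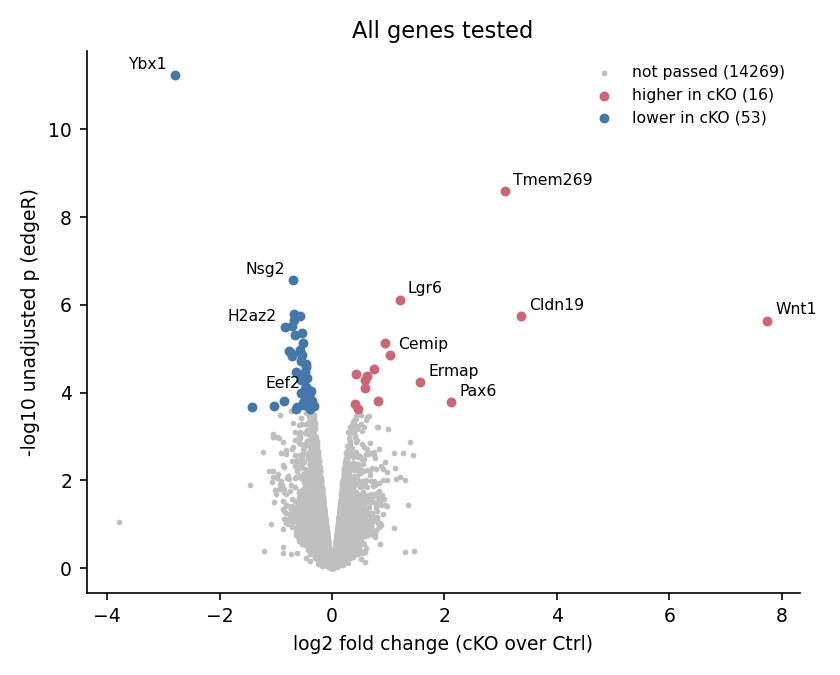
Each point is a tested gene, with its log2 fold change (cKO over Ctrl) on the horizontal axis and -log10 of the unadjusted edgeR p on the vertical axis. The 16 genes called higher and the 53 called lower are coloured; the position of Wnt1 on the horizontal axis depends on the prior count, since its counts were 0 in all 3 Ctrl libraries.

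Among called genes with at least 5 CPM, non-overlapping groups and no placeholder name, the largest rise was that of Tmem269, a gene for a transmembrane protein. It went from 1.35 ± 0.11 to 11.5 ± 2.15 normalised CPM (SD, n = 3), or 8.44-fold. Lgr6, a receptor for R-spondins, which strengthen Wnt signalling, rose 2.30-fold (log2 fold change 1.20, SE 0.13, edgeR adjusted p 0.0027). Cemip, which takes part in hyaluronan breakdown, had a log2 fold change of 1.03 (SE 0.14), and Tecta, known as a component of the tectorial membrane of the inner ear, one of 0.95 (SE 0.13). Further rises were those of the macrophage gene Mpeg1 (log2 fold change 0.82), the protease inhibitor gene Spink5 (0.75), the kinesin family gene Kif26a (0.62), the kinase gene Prkcq (0.59) and the semaphorin gene Sema3g (0.59). Adgrb1, Flot1 and Slc24a3 completed the 12, with log2 fold changes of 0.47, 0.44 and 0.41. Tmem269, Lgr6 and Tecta passed on leaving out any single library, and all 12 with the replicate block. The calls of Mpeg1, Sema3g, Adgrb1 and Slc24a3 were lost without any library other than cKO replicate 1, those of Kif26a, Prkcq and Flot1 without any numbered 2 or 3, that of Spink5 without cKO replicate 2, Ctrl replicate 2 or Ctrl replicate 3, and that of Cemip without cKO replicate 1 or Ctrl replicate 3 (edgeR adjusted p up to 0.221). With limma-voom Mpeg1, Adgrb1 and Slc24a3 did not pass, nor Adgrb1 with DESeq2 size factors. Mpeg1 belongs to a cell type whose listed genes were highest in cKO replicate 1, as described with the macrophage genes.

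Falls were ranked among called genes with at least 5 CPM, non-overlapping groups and no placeholder name. After Ybx1 the largest were those of Gng4, a G protein gamma subunit (log2 fold change -0.85, SE 0.16), and H2az2, a variant of histone H2A (-0.83, SE 0.10). H2az2 stood at 56.3 ± 6.53 CPM in Ctrl and 31.7 ± 3.26 in cKO (SD, n = 3), in a series with no group that has Cre and intact Ybx1. Nsg2, a neuronal vesicle protein gene, fell from 373 ± 5.28 to 232 ± 4.25 CPM (log2 fold change -0.69, edgeR adjusted p 0.0013). Etv4, an ETS transcription factor induced by growth factor signals, fell by 0.68 on the log2 scale (SE 0.08). Lower too were the serine protease inhibitor gene Serpina3g (log2 fold change -0.76), the GTPase gene Rem2 (-0.73), the sulfotransferase gene Chst15 (-0.72) and the tubulin-binding protein gene Tppp (-0.70). Cpne4, Plcxd2 and Stk32b had log2 fold changes of -0.67, -0.66 and -0.64. The call of Gng4 was lost with library totals, with limma-voom and without any library numbered 2 or 3 (edgeR adjusted p up to 0.191). Single removals also ended the calls of Serpina3g (cKO 2, Ctrl 2 or Ctrl 3), Stk32b (cKO 2, cKO 3 or Ctrl 3), Rem2 (cKO 2 or Ctrl 2) and Tppp (Ctrl 2 or Ctrl 3), with edgeR adjusted p up to 0.109.

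The raised genes included 3 that lie close to Ybx1 itself. Of 11 genes tested within 150 kb of Ybx1, these were Tmem269 (chromosome 4, 119205012 to 119218557), Ermap (119175457 to 119190013) and Cldn19 (119255441 to 119262438), all in GRCm38. Ermap had a log2 fold change of 1.56 (SE 0.26, edgeR adjusted p 0.0228) and Cldn19 one of 3.36 (SE 0.38, edgeR adjusted p 0.00363), from 2 to 5 counts in Ctrl libraries and 27 to 46 in cKO. The call of Ermap was lost without cKO replicate 2, Ctrl replicate 2 or Ctrl replicate 3 (edgeR adjusted p up to 0.071). The window, both of these genes and the other neighbours named were chosen after their values were seen. All 3 lie on the 3′ side of Ybx1, at 14.9 to 87.3 kb, where 8 genes were tested. None of the 3 tested on the 5′ side was called. A difference between the sides was not tested, since the genes were few and the window was chosen from them. Tmem269 and Ermap lie on the strand of Ybx1 and Cldn19 on the opposite strand. Genes between them did not pass, such as P3h1 (log2 fold change -0.26, SE 0.10) and, on the strand of Ybx1, AU022252 (-0.06, SE 0.09).

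**Figure D3:**
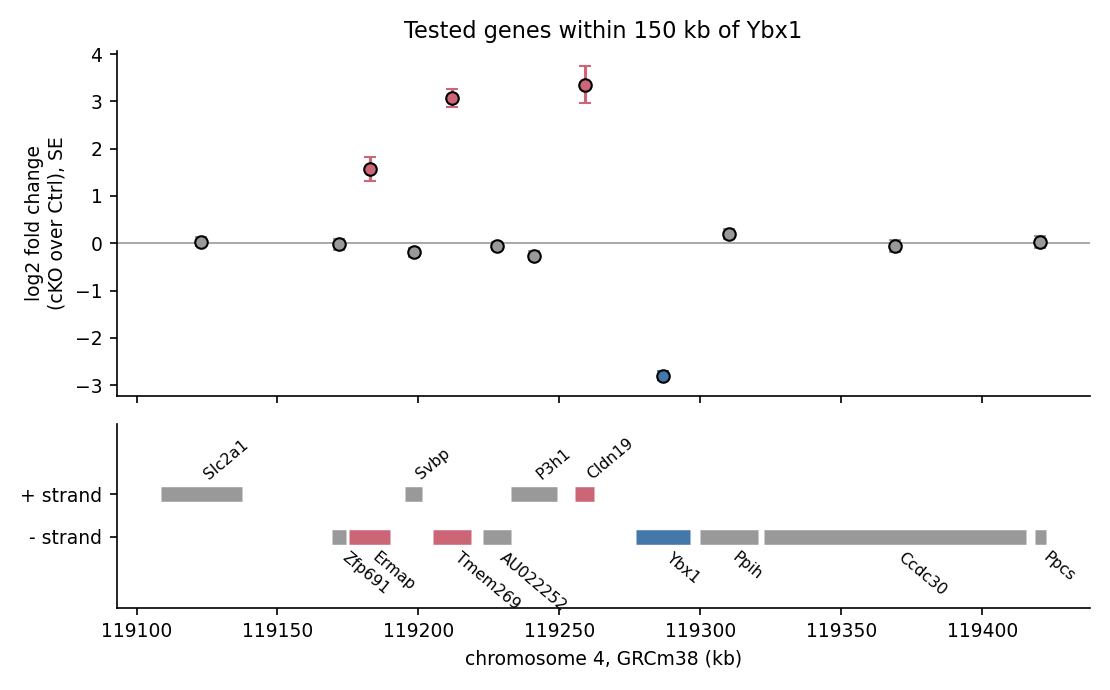
Genes tested within 150 kb of Ybx1 on chromosome 4 (GRCm38, position in kb), with their log2 fold change (cKO over Ctrl) and SE above and their extent and strand below. Red marks the 3 genes called higher, blue Ybx1, and grey the genes that did not pass.

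Transcripts of 2 elongation factors fell in cKO. The small-subunit and large-subunit ribosomal protein lists were called lower by camera with its preset correlation (adjusted p 7.44e-05 and 0.000189), and not with an estimated correlation (adjusted p = 0.877 for each). The 25 translation factor genes were not called as a list (camera adjusted p 0.139). Of these, 2 fell: Eef2, which moves the ribosome along the mRNA, from 3020 ± 104 to 2272 ± 8.03 CPM (log2 fold change -0.41, SE 0.07, edgeR adjusted p 0.0352), and Eef1g, a subunit of elongation factor 1 (-0.46, SE 0.09, edgeR adjusted p 0.045). Both calls were lost with library totals and without any library other than cKO replicate 1 (edgeR adjusted p up to 0.221). Adjusted over the list alone, 3 translation factor genes passed as lower; with the replicate block over all genes, 5 were lower and 1 higher. The log2 fold changes of the ribosomal protein genes were small, with medians of -0.12 and -0.13. They were negative for 30 of 32 small-subunit and 39 of 45 large-subunit genes, whose estimated correlations between members were 0.88 and 0.908. No member of either list passed over all genes; 1 of each passed as lower when adjusted over the list alone. With the replicate block, 12 small-subunit and 11 large-subunit genes were lower and none was higher. Together with 4 elongation factor genes, 27 of 81 were lower in that model, against 43 without litter 1, 11 without litter 2 and 18 without litter 3. The most highly expressed were Rpsa (log2 fold change -0.38, blocked edgeR adjusted p 4.80e-05), Rps2 (-0.33, 0.000232), Rplp0 (-0.48, 5.50e-06) and Rpl4 (-0.17, 0.0222). The list medians stayed negative under every scaling tried, but their size moved with single libraries. They were -0.24 and -0.21 without cKO replicate 1, -0.07 and -0.09 without cKO replicate 2, and -0.07 and -0.06 without Ctrl replicate 1, where the list calls were lost (camera adjusted p 0.0596 and 0.216).

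Genes of Schwann cells and satellite glia, the glia of the ganglia, were called higher as a list by camera with its preset correlation. Of 19 members, 16 had positive log2 fold changes, with a median of 0.19 and a camera adjusted p of 0.00182, against an adjusted p = 0.628 with an estimated correlation. No member passed over all genes; adjusted over the list alone, 5 passed as higher. With the replicate block, 8 were higher over all genes, among them the myelin gene Mbp (log2 fold change 0.31, blocked edgeR adjusted p 0.00329) and the glial transcription factor gene Sox10 (0.19, 0.0271), named after their values were seen. The 2 most highly expressed members were not called in either fit: Ngfr, the p75 neurotrophin receptor (log2 fold change -0.13), and Fabp7 (0.02). The list was higher in cKO in each of the 3 litters, by 0.17, 0.13 and 0.17 on the mean log2 scale.

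Sensory neuron genes had log2 fold changes near 0 as a list. The lists of the mechanoreceptor lineage, neurotrophin signalling and synaptic transmission were called lower by camera with its preset correlation, and not with an estimated correlation (adjusted p = 0.628, 0.877 and 0.877). The pan-neuronal list of 20 genes had a median log2 fold change of -0.04 and no called member; Nefl, a neurofilament gene, had 0.06 (SE 0.07) and Tubb3, a neuronal tubulin gene, 0.01 (SE 0.08). With the replicate block 4 of its members were lower and 1 higher. Among 12 genes of the mechanoreceptor lineage, the touch-sensing neurons, the transcription factor gene Mafa fell (log2 fold change -0.52, SE 0.10, edgeR adjusted p 0.045), a call lost with library totals, with limma-voom and without any library other than cKO replicate 1 (edgeR adjusted p up to 0.196). Adjusted over the list alone, 6 were lower and 1 higher; with the replicate block, 5 were lower, including the receptor genes Ret (-0.36, blocked edgeR adjusted p 0.000665) and Ntrk2 (-0.26, 0.00778), and Calb1 was higher (0.51, 0.0023). Ret, Ntrk2 and Calb1 were named after their values were seen. The camera adjusted p of the list was 0.0131 and, with Mafa taken out, 0.0766 (median -0.09 over 11 genes), where it was no longer called. Also called lower were neurotrophin signalling (17 genes, median -0.14, camera adjusted p 0.0101) and synaptic transmission (24 genes, median -0.08, 0.0131), neither with a called member. Adjusted over the list alone, 2 neurotrophin genes were lower, and 1 synaptic gene was higher and 1 lower; with the replicate block over all genes, 4 of each list were lower and 1 synaptic gene was higher. Without litter 1 camera no longer called these 3 lists, with or without the block, nor without cKO replicate 1 alone, and the synaptic list was also lost without Ctrl replicate 2. Without cKO replicate 1 the medians were -0.17 for the mechanoreceptor list, -0.06 for neurotrophin signalling and -0.05 for synaptic transmission. Without litter 1 and without the block they were -0.18, -0.09 and -0.04, and the synaptic median was -0.13 without cKO replicate 2, where the list was called. Among 10 genes listed for the proprioceptor lineage, the neurons that sense limb position, Etv4 was called lower; 2 were lower when adjusted over the list alone and 2 with the replicate block. None of 13 nociceptor genes, those of pain-sensing neurons, was called over all genes or over the list alone, and 1 was higher with the block.

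Genes of cholesterol synthesis were called lower as a list by camera with its preset correlation (22 genes, median log2 fold change -0.04, camera adjusted p 0.0301). With an estimated correlation the list was not called (camera adjusted p = 0.877). No member was called, over all genes or adjusted over the list alone. The list call was lost without litter 1 and on leaving out cKO replicate 1, cKO replicate 2, Ctrl replicate 1 or Ctrl replicate 3. Its median was -0.07 without cKO replicate 1, -0.06 without Ctrl replicate 1, -0.12 without cKO replicate 3 and -0.09 without Ctrl replicate 2. With library totals it was -0.015. With the replicate block 4 of its members were lower. Hmgcs1, an early enzyme of the pathway, had a log2 fold change of -0.16 (edgeR adjusted p 0.480; 0.0442 with the replicate block). Among 24 Wnt pathway genes, the list was called higher (median 0.13, camera adjusted p 0.0131; adjusted p = 0.877 with an estimated correlation), and Wnt1 was its called member, also when adjusted over the list alone. With Wnt1 taken out the other 23 genes were not called (median 0.10, camera adjusted p 0.0923). The call of the whole list was lost without cKO replicate 1 (median 0.07), without Ctrl replicate 2 (0.09) and, in the model without the block, without litter 1 (0.12). Wnt1 had 0 counts in every Ctrl library and 34, 20 and 27 in the cKO libraries, at least 26.8-fold higher against a floor of 3 counts over the Ctrl group. By the genotype labels, the Wnt1-Cre transgene was present in the cKO embryos and not in Ctrl. Reads from the transgene and a change of Wnt1 itself therefore cannot be told apart here. Of 4 tested spinal cord genes Pax6 was called, with 3, 3 and 4 counts in Ctrl and 13, 18 and 15 in cKO; adjusted over the list alone, 2 of the 4 were higher. The call of Pax6 was lost without any library other than cKO replicate 1 (edgeR adjusted p up to 0.201) and in the blocked model without litter 2. That list was called higher by camera (adjusted p 0.00352; adjusted p = 0.628 with an estimated correlation), but not with Pax6 taken out (3 genes, adjusted p 0.138). In cKO replicate 3 the spinal cord genes Lhx1, Pax2 and Lbx1, named after their values were seen, had 26, 17 and 9 counts. Each had 0 to 2 in the other libraries.

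Macrophage, erythroid and skeletal muscle genes were highest in cKO replicate 1. All 16 macrophage and leukocyte genes had positive log2 fold changes (median 0.43, camera adjusted p 7.17e-06; adjusted p = 0.877 with an estimated correlation), and none passed over all genes or adjusted over the list alone; with the replicate block 1 was higher. The list stood 0.68, 0.33 and 0.11 above Ctrl in litters 1, 2 and 3, on the mean log2 scale. The median was 0.22 without litter 1 and 0.25 without cKO replicate 1, and the list was still called. The 16 erythroid genes were not called (median 0.48, camera adjusted p 0.168): cKO replicate 1 lay 0.95 above the mean of all libraries, and Hba-a1 had 57311 counts there against 14273 to 25020 in the other libraries. The erythroid list was called higher without cKO replicate 2 (median 0.70, camera adjusted p 0.000172), cKO replicate 3 (0.62, 0.0481) or Ctrl replicate 3 (0.58, 0.042). Skeletal muscle genes were also highest in cKO replicate 1, 0.37 above the mean of all libraries. Endothelial genes (17 genes, median -0.02) and fibroblast genes (18 genes, median 0.05) were not called. The 4 Y-linked genes tested, Uty, Ddx3y, Kdm5d and Eif2s3y, were expressed in all 6 libraries and none was called.

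**Figure D4:**
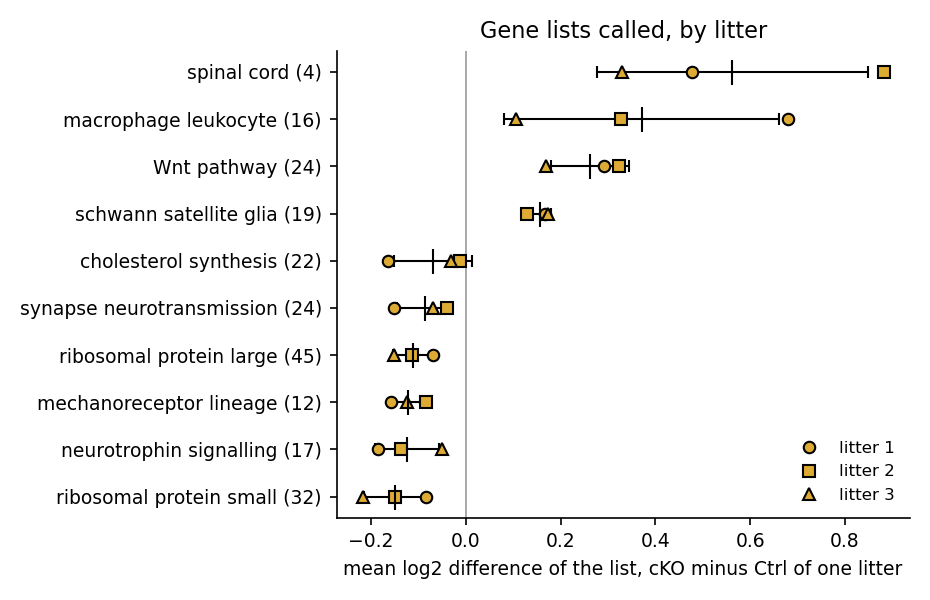
Mean log2 difference (cKO minus Ctrl, horizontal axis) of the 10 gene lists called by camera with its preset correlation, within each litter. None was called with an estimated correlation, and 5 of 10 splits of the libraries, the real one included, gave at least 10 list calls. Numbers in parentheses are genes tested, marker shapes the litters, vertical ticks the means and error bars SD over 3 litters; each list has the same sign in all 3 litters, and macrophage genes reach 0.68 in litter 1.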

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

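The settings without a litter, with a length and GC offset, with the block under other scalings or other list tests, and with called genes taken out of the lists were chosen after seeing the data. Ybx1 was called lower under every setting run, with log2 fold changes of -2.89 to -2.72 when single libraries were left out. No gene called in the main analysis changed sign under any setting. Of the 69 main calls, 66 were also called with DESeq2 size factors, 68 with DESeq2, 53 with limma-voom, 69 with no filter, 64 with the stricter filter and 44 with library totals. Below, counts are given as changed, higher and lower. DESeq2 called 184, 55 and 129 genes, and no filter gave 128, 38 and 90. Library totals gave 44 changed and 28 lower, and a fold change of at least 1.5 gave 29 changed and 16 lower, as it removes smaller changes by construction. The replicate block gave 764, 253 and 511; with DESeq2 size factors 731, 238 and 493; with library totals 799, 396 and 403; and with the length and GC offset 1141, 396 and 745. The share of lower calls in the blocked model was thus 66.9%, and 50.4% with library totals. Blocked models without litter 1 gave 1252, 520 and 732, without litter 2 260, 76 and 184, and without litter 3 836, 285 and 551. Of the 69 main calls, these models kept 69, 67 and 69. These have 1 residual degree of freedom and lean on a spread shared between genes, wholly so for most genes in the model without litter 1. With the labels of 1 litter swapped they called 1, 0 and 1 genes. Such a swap moves any real difference into the residual spread, so these counts do not measure false calls. Without litter 1 and without the block, 731, 282 and 449 genes were called, all 69 main calls among them. Leaving out single libraries, which breaks a pair, gave 18 to 104 genes changed, 6 to 39 higher and 12 to 65 lower. These single removals kept 17 to 63 of the 69 main calls. For all of these the cause was not tested. Against 10 gene lists called in the main analysis, 0 were called with an estimated correlation (3 at an unadjusted p under 0.05) and 0 with fry (7 at an unadjusted p under 0.05), 6 without litter 1 and without the block (5 of the 10 among them), and 6 to 16 when single libraries were left out (5 to 10 of the 10 among them). With the preset correlation the replicate block kept the calls of these 10 lists and called 12 in all. It added the cell cycle S list (median 0.06, camera adjusted p 0.0495) and the cell cycle G2M list (0.07, 0.0496), both higher in cKO. But in the blocked model 0 lists were called with an estimated correlation (smallest adjusted p 0.763; 0 at an unadjusted p under 0.05) and 0 with fry (smallest adjusted p 0.114; 14 at an unadjusted p under 0.05). With the genes called in the main analysis taken out of the lists, 7 of the 10 were called; the mechanoreceptor, spinal cord and Wnt pathway lists were not. In the blocked model without litter 1, Hba-a1 and Hba-a2 were lower in cKO (log2 fold changes -0.21 and -0.21) and so was the erythroid list (median -0.19), where the main values were positive and not called. At this depth changes near 1.3-fold were missed in part, so genes not called are not shown to be unchanged.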

Other observations

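Of the tests below, the length and GC test and the splits of the libraries were set out before their results were seen; the tests of gene positions, of H2az2, of blood cell RNA and of the neuron share were chosen after. With the replicate block, Trpv1, the heat and capsaicin channel of pain-sensing neurons, was higher in cKO (log2 fold change 0.40, blocked edgeR adjusted p 0.00132), as was the growth cone gene Gap43 (0.21, 0.0145). Lower in the same model were the sensory neuron transcription factor gene Isl1 (-0.21, 0.00833) and the microtubule regulator gene Stmn2 (-0.20, 0.00858). None of these 4 genes, named after their values were seen, passed in the main analysis. The abundant elongation factor gene Eef1a1, also named after its values were seen, went from 8842 ± 519 to 7403 ± 551 CPM (SD, n = 3; blocked edgeR adjusted p 0.000686). It did not pass in the main analysis.

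Of the called genes, 3 lie beside the floxed gene Ybx1, and H2az2 is known, from mouse genetics and not from these data, as the insertion site of a Wnt1-Cre transgene that may or may not be the line used. Since the window near Ybx1 was chosen from these genes, a test of chance placement would be void, and chance stays open. Transcription that runs on past the 3′ end of Ybx1 may account for them, but only 2 of the 3 lie on its strand. AU022252 lies on that strand too, between Ybx1 and Tmem269, and was not raised (log2 fold change -0.06, SE 0.09). But it held 996 to 1054 counts in Ctrl libraries, while Tmem269 went from 20 to 24 in Ctrl to 157 to 226 in cKO. The same number of added reads would move the log2 level of AU022252 far less, so this gene cannot decide. The strand setting of the counts is not known either, so run-on transcription stays open. H2az2 stood at 0.563 of its Ctrl level; the labels do not name the Wnt1-Cre line and no group has Cre with intact Ybx1, so insertion and loss of Ybx1 cannot be told apart here. Wnt1 was counted in cKO libraries alone, and only these embryos carried Cre under Wnt1 control. Reads from the transgene cannot be told apart from a change of Wnt1 itself. An effect of Ybx1 loss on these genes also stays open and untested.

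The lower levels of ribosomal protein and elongation factor transcripts in the blocked model were weighed against technical sources. With an offset for transcript length and GC content, 27 of the 27 genes called lower in the blocked model were still called lower (43, 11 and 18 were lower without litters 1, 2 and 3, with no offset). The median over 81 genes was -0.15 against -0.13 before, which argues against such a bias as the whole cause. The offset used the longest annotated transcript of each gene, which need not be the one sequenced, and a bias tied to other transcripts is not covered. More blood cell RNA in cKO replicate 1 is argued against as well, as the whole cause. Over litters 2 and 3 the ribosomal protein genes averaged -0.154, with -0.128 and -0.179 in each. The erythroid list differed by 1.01, -0.027 and -0.235 (mean log2, cKO minus Ctrl) in litters 1, 2 and 3. Less blood cell RNA in the cKO libraries of litters 2 and 3 was therefore not covered and was not tested. An effect of Ybx1 loss on the ribosomal protein and elongation factor mRNAs stays open and untested. The list calls are lost with an estimated correlation and without Ctrl replicate 1.

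A lower share of neurons in the cKO ganglia could lower many genes at once. The 52 genes called lower besides Ybx1 had a median log2 fold change of -0.51, and a neuron loss behind falls of that size would move abundant neuron genes by about as much. That median comes from genes selected by the threshold, and it was -0.29 for the genes called lower in the blocked model, Ybx1 included. The comparison therefore covers a large loss only. The pan-neuronal list instead had a median of -0.042 with an SD of 0.14 over its 20 genes, and 0 of them lay below -0.51. A smaller shift in cell makeup, for which the glial list, called higher with the preset correlation alone, would be a candidate, is not excluded by this. Nor is a loss of a single neuron class, which a pan-neuronal list does not cover. Outside that list, the neuronal genes Mapt, Ina, Kif21b and Rab3c were called lower (log2 fold changes -0.49, -0.47, -0.55 and -0.48). They were picked from the genes called lower after their values were seen. Each call was lost on leaving out some single libraries (edgeR adjusted p up to 0.2), and those of Mapt, Ina and Kif21b with library totals.

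The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 69 called genes and the highest other count was 2, so 1 split, the real one, reached that number. Of these, 4 part every litter, also too few for such a share; in the blocked model the real one gave 764 genes and the highest other count was 1, so again 1 split reached the real number. For the lists, 5 splits, the real one included, gave at least the 10 calls of the real one. The highest other count was 16, from the split that sets Ctrl 1, Ctrl 3 and cKO 1 apart. The number of list calls with the preset correlation therefore does not set the genotypes apart from other groupings of the libraries. Pax6 was 4.40, 5.97 and 3.63 times as high in cKO as in Ctrl in litters 1, 2 and 3, while the other listed spinal cord genes, summed, were 1.16, 1.32 and 1.87 times as high. Gdf1 and Cers1, noticed from their values, overlap on chromosome 8 and their counts switched between libraries, with 407, 2 and 323 for Gdf1 in Ctrl and 45, 0 and 9 in cKO, while their sum lay between 323 and 407 in all 6, so neither is reported as changed.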
